A study of Mus musculus with 15 samples.

How the data were processed

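The data were bulk RNA-seq libraries of CD206-positive cells from the dura mater of C57BL/6J mice that carried 1 Cx3cr1-GFP allele, taken at embryonic day 14.5 (E14.5) and at postnatal days 3, 10, 21 and 56 (P3, P10, P21 and P56), with 3 libraries per age and 15 libraries in all. Per the labels' protocols, sorted cells were collected in RNAprotect, RNA was extracted with PicoPure, cDNA was made with the SMARTer Ultra Low Input v4 kit, and libraries were made with Nextera XT. The values used were the deposited raw read counts per gene symbol, with no normalization. The submitters' processing notes name bcl2fastq 2.18, STAR 2.7.8a and featureCounts 2.0.2. They give no genome build, annotation, strand setting or rule for reads that map to several genes, so no coordinates are given and values of near-identical genes are uncertain. Of the 53546 symbols in the count table, 50067 (93.5%) matched GENCODE M21. The labels put the P56 libraries in one sequencing project and the other 4 ages in another.

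Total counts ranged from 17550170 to 30614583 per library, and 11254 to 13654 genes had at least 10 counts. The protocols name no molecular identifiers, so intervals and floors (3 counts over an age) cover counting error only. Levels of single genes are given as CPM scaled by TMM, counts divided by the total of the tested genes times the TMM factor of the library, as mean ± SD over the 3 libraries of an age. The TMM factors were 1.123 to 1.158 at E14.5 and 0.8071 to 0.8565 at P56, so these levels differ from shares of the total count. Sums over a list, and levels given as CPM of the total, are counts divided by the total count of the library with no TMM factor.

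Genes were tested with edgeR 4.0.16 in R 4.3.3. All 15 libraries entered 1 fit with age as the only term, with TMM scaling, the filterByExpr filter by age (14683 genes kept) and robust quasi-likelihood F-tests. P-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, and a gene was called changed at an adjusted p under 0.05. Log2 changes are given with the SE from the fit. The comparisons were P3 vs E14.5, P10 vs P3, P21 vs P10, P56 vs P21 and P21 vs E14.5. A further F-test of any difference used only the 12 libraries of E14.5, P3, P10 and P21, which share a sequencing project. P-values measure the spread between libraries labelled as replicates, and the series text gives 3 to 5 individual mice per age.

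The comparisons, tests, 38 gene lists and the rule for naming genes were fixed before the data were examined. The named genes were, for each comparison, up to 10 genes with the largest rise and 10 with the largest fall. They had to be called, to reach a mean of 20 CPM in the higher age, to show no overlap between the libraries of both ages, and to bear a symbol that is not a predicted model, a pseudogene, a ribosomal protein or a mitochondrial gene. Up to 4 members with the smallest p of each list that passed its test, and 5 identity genes, were also named. Lists with at least 5 tested genes (37 of 38) were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, two-sided, adjusted over the lists of a comparison. Camera was repeated with an estimated correlation, and fry was run as a self-contained test. Some lists share members, so their results are not independent. Mrc1, Cd163 and Cd209f are in both the border-associated macrophage and the alternative activation lists, and Cd163 is also in the glucocorticoid response list. Counts given as "adjusted over the list alone" adjust the edgeR p-values over the members of a list only.

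The tests were checked on simulated data: counts of 200 genes were changed by 2, 4 or 8-fold, and 1.22% to 4.44% of the calls were false. Counts were drawn independently for each gene, with the same spread at all ages, and the changed genes were picked above a minimum mean count. The real spread differed between ages, with r between libraries of 0.93 to 0.948 at E14.5 and 0.843 to 0.896 at P21. These rates therefore need not hold for the real comparisons. The fit called 5.97% to 13.4% of the genes changed 2-fold, 43.9% to 50.7% of those changed 4-fold and 62.1% to 65.2% of those changed 8-fold. Alternatives tried were other scalings (RLE, upper quartile), no filter and a filter of 5 CPM in 3 libraries, libraries thinned to the smallest total, fits of only the ages compared, the replicate number as a block, leaving out each library in turn, an added log2 change of at least 1, limma voom and DESeq2 1.42.0. Levels of genes of the sex-linked list are not given. The list of T and NK cell markers was left untested because it had under 5 tested genes. No count column was left out.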

Results

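All values below compare older with younger libraries, with n = 3 per age. The dura is the outer membrane of the brain, and CD206, the sorted protein, is encoded by Mrc1. Mrc1 passed the test in none of the 5 comparisons, with 2573 ± 128 CPM at E14.5, 2182 ± 298 at P3, 2056 ± 389 at P10, 2773 ± 647 at P21 and 3075 ± 1249 at P56 on the TMM scale. As CPM of the total, without TMM, 2935 ± 184.5 at E14.5 was above 2551 ± 1013 at P56, so the order of these ages turns with the scale. Csf1r, the receptor gene for the growth factor that macrophages depend on, passed in none either, with 4251 ± 363 CPM at E14.5 and 6887 ± 3038 at P56, or 4850 ± 471.5 and 5707 ± 2444 as CPM of the total. Cx3cr1, which had 1 of its alleles replaced by GFP in these mice, had 713 ± 146 CPM at E14.5 and 418 ± 97.7 at P3, a difference that did not pass (log2 change -0.77, adjusted p = 0.0794). Ptprc, the CD45 gene, had 160 ± 38.7 CPM at P10 and 251 ± 25.8 at P21 and did not pass (0.65, adjusted p = 0.0572), but it passed without P10 replicate 3 (0.87, adjusted p = 0.0127). Adgre1, the F4/80 gene, rose from 1423 ± 174 CPM at E14.5 to 2092 ± 33.2 at P21 (log2 change 0.56 ± 0.14, adjusted p = 0.0158), or from 1625 ± 220.7 to 1923 ± 53.22 as CPM of the total, a smaller difference. That call was lost without E14.5 replicate 1 (adjusted p = 0.0814) and without P21 replicate 2 (0.0522).

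Among the 12 libraries from E14.5 to P21, 1759 of 14287 tested genes differed between ages, and 1225 of them spanned at least 2-fold. Their highest mean lay at E14.5 for 592 genes, at P3 for 104, at P10 for 281 and at P21 for 782. The count was 1009 without E14.5 replicate 2 and 1112 without E14.5 replicate 3. The first principal component of all 15 libraries, with 22.6% of the variance, had mean scores of -92.6 ± 0.7 at E14.5, -48.7 ± 2.5 at P3, -5.8 ± 6.3 at P10, 73.2 ± 59.9 at P21 and 73.8 ± 11.6 at P56. The P21 mean rests on P21 replicate 2, with a score of 138.73 beside 59.69 and 21.29 for replicates 1 and 3. That library also lay apart on the second component, with a score of 155.9.

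**Figure D1:**
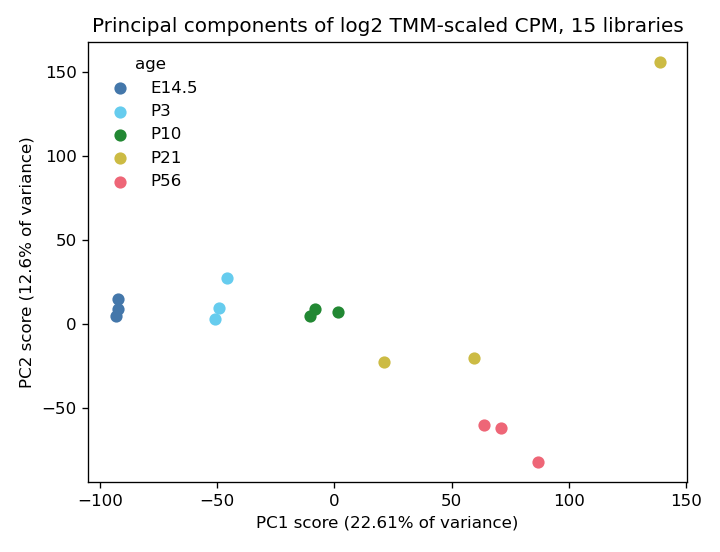
Principal component scores of log2 TMM-scaled CPM, 1 point per library, coloured by age. E14.5, P3 and P10 libraries lie in that order along the first component, and P21 replicate 2 lies apart at 155.9 on the second.

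**Figure D2:**
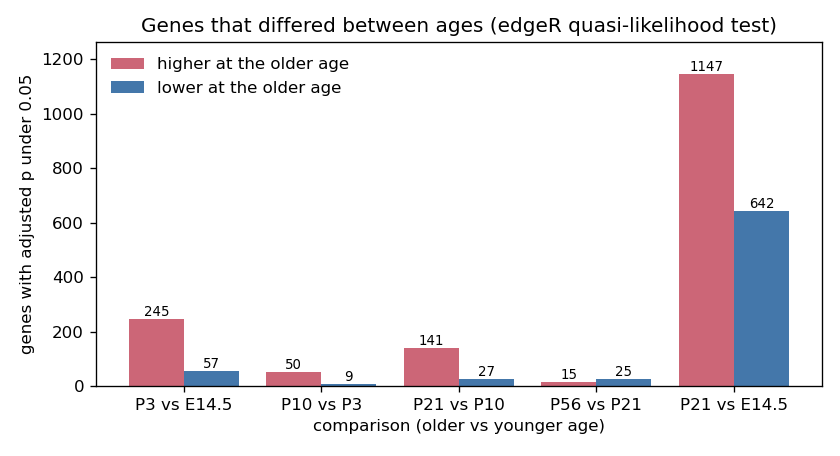
Number of genes with an adjusted p under 0.05 in each comparison, as bars for genes higher or lower at the older age. P21 vs E14.5 had the most, with 1147 higher and 642 lower.

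From E14.5 to P3, genes of border macrophages and of antigen presentation on MHC class I rose, while DNA replication and glycolysis genes fell. Cbr2, a carbonyl reductase gene used as a marker of these macrophages, rose by 5.01 ± 0.14 on the log2 scale, from 19.3 ± 0.796 to 622 ± 82.3 CPM (adjusted p = 4.33e-11). Cd163, the scavenger receptor gene for hemoglobin bound to haptoglobin, rose by 3.90 ± 0.36, from 39.6 ± 14.8 to 590.4 ± 31.9 CPM (adjusted p = 7.46e-05). The lectin genes Cd209f (5.58 ± 0.43, adjusted p = 1.25e-05) and Cd209g (8.04 ± 0.79, adjusted p = 0.000114) also rose, though reads shared within this gene family make the value of each uncertain. Egr1, an immediate early transcription factor gene, fell by 2.02 on the log2 scale (SE 0.17), from 5054 ± 219 to 1249 ± 169 CPM (adjusted p = 2.5e-05). In all, 302 of 14683 genes changed, 245 up and 57 down, of which 156 and 30 moved at least 2-fold. The libraries of both ages did not overlap for 3879 genes (26.4%), where chance gives 10%.

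Of 14 tested MHC class I genes, which load peptides for display to T cells, 7 rose, and 12 did so adjusted over the list alone (median log2 change 0.98, camera adjusted p = 1.18e-17). H2-D1 rose by 1.64 ± 0.11 to 2190 ± 139 CPM and H2-K1 by 1.83 ± 0.15 to 1129 ± 70.8 CPM, with the caution that MHC genes share reads. B2m, their common light chain, rose by 1.1 ± 0.14 (adjusted p = 0.000873). Border-associated macrophage markers rose in 8 of 22 tested members and fell in 1, and 13 rose and 2 fell adjusted over the list alone (median 0.77, camera adjusted p = 1.25e-10). F13a1, a transglutaminase gene that was chosen after its values were seen, was the member that fell (log2 change -0.91, adjusted p = 0.0225). Interferon-stimulated genes rose in 8 of 22 members, 10 adjusted over the list alone (median 0.86, camera adjusted p = 4.6e-10), with Ifitm3, an antiviral membrane protein gene, up by 1.73 ± 0.17. MHC class II genes rose in 5 of 13 members, 9 adjusted over the list alone (median 1.89, camera adjusted p = 5.41e-08). Their invariant chain gene Cd74 rose by 1.75 ± 0.25, from 53.5 ± 2.47 to 180.0 ± 44.5 CPM. Complement genes rose in 3 of 14 members, with 6 up and 1 down adjusted over the list alone (median 0.66, camera adjusted p = 1.12e-06). Cfp, the properdin gene, rose by 1.83 ± 0.11, from 181 ± 18.2 to 642 ± 17.9 CPM. Alternative activation genes (5 of 11 up, 5 up and 1 down adjusted over the list alone, median 1.12, camera adjusted p = 4.88e-07), lysosome genes (3 of 20, 4 adjusted over the list alone, median 0.35, camera adjusted p = 5.59e-08) and core macrophage genes (2 of 18, with 7 up and 1 down adjusted over the list alone, median 0.40, camera adjusted p = 2.79e-05) also moved up. Lyz2, the lysozyme gene, rose by 1.27 ± 0.16, from 1725 ± 87.5 to 4155 ± 664 CPM.

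DNA replication genes fell in 3 of 24 tested members, 7 adjusted over the list alone (median -0.82, camera adjusted p = 1.37e-09). Glycolysis genes fell in 6 of 16, 9 adjusted over the list alone (median -0.62, camera adjusted p = 5.02e-09). Pkm, the pyruvate kinase gene, fell by 0.82 on the log2 scale (SE 0.14), from 622 ± 13.3 to 353 ± 2.12 CPM (adjusted p = 0.00633). These 10 lists kept their call with an estimated correlation between genes, but with camera adjusted p of 0.00445 to 0.0336, far larger than at the preset correlation of 0.01. The other 11 of the 21 lists called did not keep it. Mitosis genes, lower with 0 of 23 members called by edgeR (median -0.78, camera adjusted p = 6.08e-05), had adjusted p = 0.294 with an estimated correlation. Glucocorticoid response genes (2 of 13 up, 6 adjusted over the list alone) had adjusted p = 0.158 with an estimated correlation. Chemokine and cytokine genes (8 of 24 up, 1 down) had adjusted p = 0.132 with an estimated correlation, with Il1b, an inflammatory cytokine gene, up by 1.27 ± 0.15. Mast cell markers (1 of 9 up, 5 adjusted over the list alone) had a median of 5.92, or 5.08 with members at the floor set to their bound, and adjusted p = 0.0654 with an estimated correlation. Their sums ranged from 2.11 to 126 CPM of the total at E14.5. Without E14.5 replicate 1, Tpsb2 (edgeR adjusted p = 0.033) and Cma1 (0.0124) gained a call, so the size of this change depends on that library. Fibroblast markers (1 of 14 up, 8 adjusted over the list alone, median 2.32) had adjusted p = 0.0956 with an estimated correlation.

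The 302 genes became 178, 127 and 198 without E14.5 replicates 1, 2 and 3, and 192, 146 and 162 without P3 replicates 1, 2 and 3. They became 22 without 2 of the 3 E14.5 libraries, which differed from the other libraries in genes of the sex-linked list, 31 with the summed fibroblast markers as a covariate and 34 with the summed mast cell markers; with these covariates a median share of 0.99 and 1.04 of the log2 change stayed, 302 of 302 genes kept their sign, and the median SE grew from 0.22 to 0.32 and 0.37. Of the 19 genes with the largest changes, 6 kept their call without each of the 6 libraries (Cbr2, Cd209f, Cd209g, Cpz, Egr1 and Gsta4).

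From P3 to P10, immediate early genes, MHC class II genes and the chemokine gene Ccl8 rose, and DNA replication genes fell further. Btg2, an immediate early gene that restrains division, rose by 1.89 ± 0.19, from 597 ± 114 to 2204 ± 331 CPM (adjusted p = 0.000393). Ccl8, a gene for a monocyte attractant, rose by 3.74 ± 0.40, from 20.8 ± 10.3 to 277 ± 92.1 CPM (adjusted p = 0.000782). Cd74 rose by 2.05 ± 0.25, from 180.0 ± 44.5 to 747 ± 272 CPM (adjusted p = 0.00255). Hgsnat, which encodes a lysosomal acetyltransferase, fell by 0.94 on the log2 scale (SE 0.13), from 1044 ± 108 to 542 ± 64.9 CPM (adjusted p = 0.0055). In all, 59 genes changed, 50 up and 9 down, of which 32 and 5 moved at least 2-fold. The libraries did not overlap for 2812 genes (19.2%), against 10% by chance.

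Immediate early and heat shock genes rose in 7 of 21 tested members, 12 adjusted over the list alone (median 0.64, camera adjusted p = 1.5e-19). Fos rose by 1.01 ± 0.14, from 2128 ± 141 to 4301 ± 384 CPM, and Dusp1, a phosphatase gene induced with it, by 1.17 ± 0.10, from 964 ± 48.3 to 2167 ± 234 CPM. From E14.5 to P3, Dusp1 had fallen by 0.74 on the log2 scale (SE 0.10, adjusted p = 0.00107). MHC class II genes rose in 3 of 13 members, 7 adjusted over the list alone (median 1.32, camera adjusted p = 2.91e-06). Alternative activation genes rose in 3 of 11, with 6 up and 1 down adjusted over the list alone (median 0.64, camera adjusted p = 0.000125), with the lectin gene Mgl2 up by 1.01 ± 0.14, from 133 ± 18.5 to 267 ± 24.8 CPM. Core macrophage genes (2 of 18 up, 3 adjusted over the list alone, median 0.23, camera adjusted p = 0.000318), microglia markers (1 of 11, with 5 up and 1 down adjusted over the list alone, median 0.31, camera adjusted p = 0.000281) and dendritic cell markers (1 of 11, also 1 adjusted over the list alone, median 0.88, camera adjusted p = 0.00339) moved up. DNA replication genes fell in 1 of 24 members, 7 adjusted over the list alone (median -0.72, camera adjusted p = 1.25e-09).

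These 7 lists kept their call with an estimated correlation, of 24 called, with camera adjusted p of 0.0233 to 0.0358. Chemokine and cytokine genes (3 of 24 up, with 9 up and 1 down adjusted over the list alone) had adjusted p = 0.0801 with an estimated correlation. Il1b rose by 1.06 ± 0.15 (adjusted p = 0.0055) and Cxcl16, a membrane-bound chemokine gene, by 1.24 ± 0.18 (adjusted p = 0.00661). Interferon-stimulated genes, lower with 0 of 22 members called by edgeR and 2 adjusted over the list alone (median -0.39), had adjusted p = 0.202 with an estimated correlation. Mitosis genes (median -0.71) had adjusted p = 0.229 with an estimated correlation. Lists of other cell types also shifted, each with 0 or 1 member called by edgeR. Neutrophil markers (median -2.91, camera adjusted p = 0.00513), erythroid markers (-1.28, 0.0124) and glia markers (1.54, 0.0355) each had adjusted p = 0.22 with an estimated correlation. Summed neutrophil markers overlapped between these ages, from 24.2 to 245 CPM of the total at P3 and from 14.2 to 38 at P10. Mast cell markers (-1.8, camera adjusted p = 0.0139) had adjusted p = 0.405 with an estimated correlation, and fibroblast markers (0.49, 0.0285) had 0.512. B cell markers, tested as higher (median 0.18, mean -0.46, camera adjusted p = 0.0124), had adjusted p = 0.0801 with an estimated correlation. The erythroid call was lost without P10 replicates 1 (0.0653) and 2 (0.0542), and those of glia (0.109) and B cell markers (0.0643) without P10 replicate 3. The mast cell call was lost without P3 replicate 2 (0.0646) and P10 replicate 3 (0.0551), and the fibroblast call without P3 replicates 1 (0.411) and 2 (0.054) and P10 replicates 1 (0.227) and 3 (0.109).

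The 59 genes became 24, 30 and 21 without P3 replicates 1, 2 and 3, and 38 and 22 without P10 replicates 1 and 2. Of the 19 genes with the largest changes, 4 kept their call without each of the 6 libraries (Btg2, Ccl8, Cd74 and Hgsnat).

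From P10 to P21, glucocorticoid response, interferon-stimulated, MHC class II and complement genes rose. Tsc22d3, the gene for the glucocorticoid-induced leucine zipper, rose by 2.92 ± 0.26, from 226 ± 40.9 to 1713 ± 514 CPM (adjusted p = 0.000149). Vcam1, a cell adhesion gene, rose by 2.91 ± 0.40, from 190.2 ± 20 to 1426 ± 513 CPM (adjusted p = 0.00325). Cd74 rose by 2.50 ± 0.25, to 4219 ± 588 CPM (adjusted p = 0.000589), and Mgl2 by 1.96 ± 0.14, to 1041 ± 155 CPM (adjusted p = 2.63e-05). Cdca8, a chromosome segregation gene, fell by 1.32 on the log2 scale (SE 0.21), from 74.6 ± 13 to 29.8 ± 7.23 CPM (adjusted p = 0.00758), a call lost without P10 replicate 1 (adjusted p = 0.0508). In all, 168 genes changed, 141 up and 27 down, of which 93 and 18 moved at least 2-fold. The libraries did not overlap for 2602 genes (17.7%), against 10% by chance.

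Glucocorticoid response genes rose in 4 of 13 tested members, 12 adjusted over the list alone (median 1.51, camera adjusted p = 1.79e-15). Errfi1, a gene for a brake on EGF receptor signalling, rose by 1.82 ± 0.24, from 70.3 ± 11.6 to 249 ± 44.7 CPM (adjusted p = 0.00299). Fkbp5, a chaperone gene of the glucocorticoid receptor, rose by 3.79 ± 0.64, from 11.3 ± 1.67 to 156 ± 73.4 CPM (adjusted p = 0.0142), a call lost without P10 replicates 1 (0.085), 2 (0.0764) and 3 (0.0562). Interferon-stimulated genes rose in 3 of 22 members, 17 adjusted over the list alone (median 1.19, camera adjusted p = 5.77e-17), with Ifitm3 up by 1.59 ± 0.17, from 227 ± 24.1 to 685 ± 65.6 CPM. MHC class II genes rose in 5 of 13, 6 adjusted over the list alone (median 1.94, camera adjusted p = 1.23e-11). Complement genes rose in 6 of 14, 7 adjusted over the list alone (median 0.81, camera adjusted p = 1.24e-10). C1qb, for a chain of the first complement component, rose by 0.72 ± 0.10, from 6402 ± 688 to 10520 ± 839 CPM, and Cfp by 0.80 ± 0.10, from 720.1 ± 11.3 to 1251 ± 50.5 CPM. Border-associated macrophage markers (3 of 22 up, 5 adjusted over the list alone, median 0.48, camera adjusted p = 1.81e-08), MHC class I genes (3 of 14, 6 adjusted over the list alone, median 0.48, camera adjusted p = 1.73e-07), alternative activation genes (2 of 11, 3 adjusted over the list alone, median 0.45, camera adjusted p = 3.42e-06) and core macrophage genes (1 of 18, 6 adjusted over the list alone, median 0.43, camera adjusted p = 3.7e-06) moved up. Cbr2 rose by 1.11 ± 0.12, from 1400 ± 145 to 3018 ± 238 CPM (adjusted p = 0.000596).

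These 8 lists kept their call with an estimated correlation, of 20 called, with camera adjusted p of 0.00113 to 0.043. Immediate early and heat shock genes (7 of 21 up, with 13 up and 1 down adjusted over the list alone, median 0.84) had adjusted p = 0.06 with an estimated correlation. Klf2, a transcription factor gene that restrains activation, rose by 1.83 ± 0.25, from 128 ± 29.3 to 455 ± 121 CPM (adjusted p = 0.0031). Osteoclast genes, lower with 1 of 8 members called and 5 adjusted over the list alone (median -2.60, camera adjusted p = 7.8e-07), had adjusted p = 0.0771 with an estimated correlation. Among them Ctsk, a collagen-degrading protease gene, had 528 ± 226 CPM at P10 and 31.2 ± 14.8 at P21 and did not itself pass. Oxidative phosphorylation genes (0 of 26 called by edgeR, 17 lower adjusted over the list alone, median -0.47) had adjusted p = 0.135 with an estimated correlation. Ribosomal protein genes, whose reads are shared with pseudogenes (0 of 30 called by edgeR, 12 lower adjusted over the list alone, median -0.53), had adjusted p = 0.19 with an estimated correlation. Mitosis genes (1 of 23 lower, 7 adjusted over the list alone, median -0.87) had adjusted p = 0.124 with an estimated correlation. Dendritic cell markers (2 of 11 up, with 3 up and 1 down adjusted over the list alone, median 1.29, camera adjusted p = 0.0192) had adjusted p = 0.0703 with an estimated correlation. Their call was lost without P10 replicates 2 (0.0563) and 3 (0.0967) and P21 replicate 3 (0.0744), and their sum was 473 ± 37.2 CPM of the total at P10 and 930 ± 37.3 at P21. The most abundant of these markers at P21 was Clec10a, which is also in the alternative activation list, so this sum need not reflect dendritic cells. Mast cell markers, lower with 0 of 9 members called by edgeR and 4 adjusted over the list alone, had a median of -4.55, or -4.44 with members at the floor set to their bound (camera adjusted p = 3.21e-05). They had adjusted p = 0.16 with an estimated correlation, and their sum was 292 ± 132 CPM of the total at P10 and 8.5 ± 3.92 at P21.

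The 168 genes became 30, 45 and 85 without P10 replicates 1, 2 and 3, and 101 and 69 without P21 replicates 1 and 2. With the summed mast cell markers as a covariate 6 genes were called, all among the 168, while a median share of 1.02 of the log2 change stayed and the median SE grew from 0.23 to 0.32. Of the 20 genes with the largest changes, only Tsc22d3 and Vcam1 kept their call without each of the 6 libraries.

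**Figure D3:**
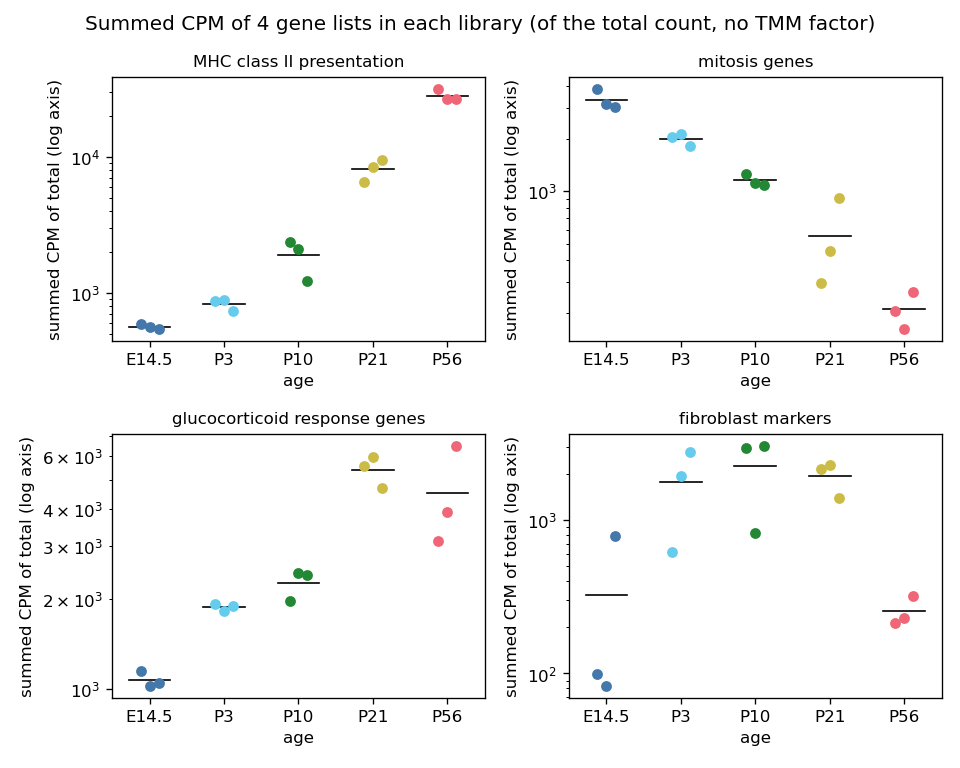
Summed CPM of the total for 4 gene lists, with no TMM factor (log axis), 1 point per library, with a line at the mean of each age. MHC class II genes rise from a mean of 566 CPM at E14.5 to 28300 at P56, mitosis genes fall from 3350 to 210.0, and fibroblast markers vary within ages.

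Between P21 and P56, the MHC class II pathway genes Cd74, H2-DMa and H2-DMb1 were higher, and Birc5, Uhrf1 and DNA replication genes were lower. P56 is also the sole age in its sequencing project, so age and project cannot be told apart here. Cd74 was higher by 1.85 ± 0.25, with 4219 ± 588 CPM at P21 and 15250 ± 1445 at P56 (adjusted p = 0.00746). H2-DMa and H2-DMb1, which help to load peptides on MHC class II, were higher by 1.79 ± 0.19 (155 ± 12.4 and 537 ± 119 CPM, adjusted p = 0.00278) and 1.71 ± 0.24 (adjusted p = 0.0075). S1pr1, a receptor gene for a lipid that guides cell exit from tissue, was higher by 1.08 ± 0.13 (119 ± 3.39 and 251 ± 21.8 CPM, adjusted p = 0.00456), and Axl, a receptor gene for the uptake of dying cells, by 1.64 ± 0.26 (adjusted p = 0.0161). Birc5, a gene needed for cell division, fell by 1.77 on the log2 scale (SE 0.23), from 51.0 ± 5.49 to 15 ± 5.16 CPM (adjusted p = 0.00612). Gja1, which encodes connexin 43, fell by 2.53 on the log2 scale (SE 0.33, adjusted p = 0.00612), and Uhrf1, a gene for keeping DNA methylation through replication, by 2.30 (SE 0.32, adjusted p = 0.0075). In all, 40 genes changed, 15 higher and 25 lower at P56, of which 11 and 24 moved at least 2-fold. The libraries did not overlap for 1906 genes (13%), against 10% by chance.

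DNA replication genes were lower in 3 of 24 tested members, 9 adjusted over the list alone (median -0.80, camera adjusted p = 2.74e-09). Mcm5, a replicative helicase gene, fell by 1.24 on the log2 scale (SE 0.17), from 92.3 ± 18.6 to 39.1 ± 4.94 CPM (adjusted p = 0.0075). Fetal growth and imprinted genes were lower in 1 of 14, 4 adjusted over the list alone (camera adjusted p = 4.48e-07), with a median of -2.21, or -1.63 with members at the floor set to their bound. Complement genes were higher with 0 of 14 called by edgeR and 5 adjusted over the list alone (median 0.34, camera adjusted p = 0.000393). These 3 lists kept their call with an estimated correlation, of 11 called, each with a camera adjusted p of 0.0278. No list was tested with the summed fibroblast markers as a covariate. MHC class II genes (3 of 13 higher, 6 adjusted over the list alone, median 1.74, camera adjusted p = 4.19e-06) had adjusted p = 0.0633 with an estimated correlation. Mitosis genes (1 of 23 lower, 12 adjusted over the list alone, median -1.15) had adjusted p = 0.143 with an estimated correlation. Fibroblast markers (0 of 14 called by edgeR, 8 lower adjusted over the list alone, median -2.78) had adjusted p = 0.143 with an estimated correlation.

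Mast cell markers, higher with 0 of 9 called by edgeR and 0 adjusted over the list alone (median 4.37, or 3.6 with members at the floor set to their bound, camera adjusted p = 0.042), had adjusted p = 0.53 with an estimated correlation. They rest on P56 replicate 5, with a sum of 291.7 CPM of the total beside 10.2 and 15.69, and lost their call without it (0.874) and without P21 replicates 1 (0.0799), 2 (0.0801) and 3 (0.0766). P56 replicate 4 stood apart from P56 replicates 5 and 6, with summed monocyte markers of 621.5 CPM of the total beside 167.2 and 232.8, mitochondrially encoded genes of 5988 beside 3322 and 3007, Csf1r of 2892 beside 7296 and 6932, and MHC class II genes of 31660 beside 26610 and 26770. Mrc1, the gene of the sorted protein, was also lower in P56 replicate 4, at 1416 CPM of the total beside 3364 and 2874. Its summed border-associated macrophage markers were 55870 beside 74900 and 73360.

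The 40 genes became 100 without P21 replicate 3, and the 11 lists became 7 without P21 replicate 3 and 18 without P56 replicate 4. A fit of these 6 libraries alone called 3 genes, of which 1 was among the 40, a fit with the summed mast cell markers as a covariate called 23, and with the summed fibroblast markers as a covariate edgeR called 0 genes (802 at an unadjusted p under 0.05), where DESeq2 without the covariate called 528. With that covariate a median share of 0.98 of the log2 change stayed and the median SE grew from 0.25 to 0.36.

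Over the span from E14.5 to P21, inside 1 sequencing project, 1789 genes changed, 1147 up and 642 down, of which 775 and 411 moved at least 2-fold. The libraries did not overlap for 4911 genes (33.4%), against 10% by chance. Ccl8 rose by 8.29 ± 0.51, from 1.47 ± 0.608 to 457 ± 35.8 CPM (adjusted p = 1.44e-07). Cbr2 rose by 7.29 ± 0.15, from 19.3 ± 0.796 to 3018 ± 238 CPM (adjusted p = 1.04e-12), and Mgl2 by 4.09 ± 0.16, from 60.9 ± 6.86 to 1041 ± 155 CPM (adjusted p = 1.45e-09). Cd209b had 3 counts over the E14.5 libraries, and its ratio of 2160 has a 95% counting interval of 739 to 10500. Igf2bp1, a fetal RNA-binding protein gene, fell by 7.63 on the log2 scale (SE 1.16), from 40.8 ± 12.7 to 0.202 ± 0.138 CPM (adjusted p = 0.000583). Spp1, the osteopontin gene, fell by 3.97 on the log2 scale (SE 0.72), from 534 ± 167 to 34.1 ± 22.7 CPM (adjusted p = 0.00225). The hemoglobin genes Hbb-bs and Hbb-bt, which share reads, had log2 changes of -5.49 (SE 0.97, adjusted p = 0.00184) and -6.16 (SE 1.26, adjusted p = 0.00532). Of the 19 genes with the largest changes, 15 kept their call without each of the 6 libraries, Ccl8, Cd209b, Igf2bp1, Spp1 and both hemoglobin genes among them.

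MHC class II genes rose in 8 of 13 tested members, 10 adjusted over the list alone (median 4.75, also with members at the floor set to their bound, camera adjusted p = 2.11e-14). Cd74 rose by 6.30 ± 0.30, from 53.5 ± 2.47 to 4219 ± 588 CPM (adjusted p = 1.58e-08), and passed the test at each of the 4 steps from E14.5 to P56. H2-Aa, for an alpha chain of MHC class II, rose by 8.62 ± 0.87, from 3.17 ± 3.72 to 1222 ± 363 CPM (adjusted p = 1.96e-05). MHC class I genes rose in 12 of 14, also 12 adjusted over the list alone (median 1.25, camera adjusted p = 2.11e-14), and interferon-stimulated genes in 14 of 22, 16 adjusted over the list alone (median 1.70, camera adjusted p = 3.77e-13). Glucocorticoid response genes rose in 11 of 13, 13 adjusted over the list alone (median 2.72, camera adjusted p = 6.31e-15), with Tsc22d3 up by 3.92 ± 0.27 and Mt2, a metal-binding protein gene close in sequence to Mt1, up by 4.67 ± 0.56. Chemokine and cytokine genes rose in 14 of 24 and fell in 2, with 16 up and 2 down adjusted over the list alone (median 1.78, camera adjusted p = 2.04e-10). Il1b rose by 3.65 ± 0.16, from 188 ± 14.8 to 2362 ± 209 CPM (adjusted p = 8.48e-09). Complement (9 of 14, median 1.55), core macrophage (12 of 18, median 0.71), alternative activation (8 of 11 up, 1 down, median 3.63) and lysosome genes (10 of 20, median 0.39) also moved up. Border-associated macrophage markers were mixed: 14 of 22 rose and 3 fell, with 15 up and 4 down adjusted over the list alone (median 1.25, camera adjusted p = 7.73e-11). C1qa rose by 2 ± 0.10, from 1295 ± 64.4 to 5173 ± 137 CPM, and Lyz2 by 2.83 ± 0.17, from 1725 ± 87.5 to 12250 ± 1376 CPM.

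Mitosis genes fell in 18 of 23 tested members, 22 adjusted over the list alone (median -2.44, camera adjusted p = 3.07e-15), and DNA replication genes in 17 of 24, 21 adjusted over the list alone (median -1.96, camera adjusted p = 4.37e-16). Cdk1, the kinase gene that starts mitosis, fell by 1.99 on the log2 scale (SE 0.27), from 282 ± 45.6 to 71.1 ± 19.2 CPM (adjusted p = 0.000217). Glycolysis genes fell in 11 of 16, 12 adjusted over the list alone (median -0.96, camera adjusted p = 6.5e-08), with log2 changes of -1.67 ± 0.14 for Pkm and -1.43 ± 0.18 for Ldha, the lactate dehydrogenase gene. All lists named so far for this span kept their call with an estimated correlation, among 17 of the 22 called, with camera adjusted p of 0.000718 to 0.0301. Fibroblast markers (7 of 14 up, 9 adjusted over the list alone, median 2.96) had adjusted p = 0.118 with an estimated correlation. Erythroid markers (4 of 12 down, median -3.92, or -2.76 with members at the floor set to their bound) had adjusted p = 0.162 with an estimated correlation and lost their call without E14.5 replicate 1 (0.0536). The 1789 genes became 382 with the summed fibroblast markers as a covariate, with which a median share of 0.99 of the log2 change stayed, 1789 of 1789 genes kept their sign, and the median SE grew from 0.26 to 0.41. They became 1108 without E14.5 replicate 2, and 374 without 2 of the 3 E14.5 libraries, which differed from the other libraries in genes of the sex-linked list.

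**Figure D4:**
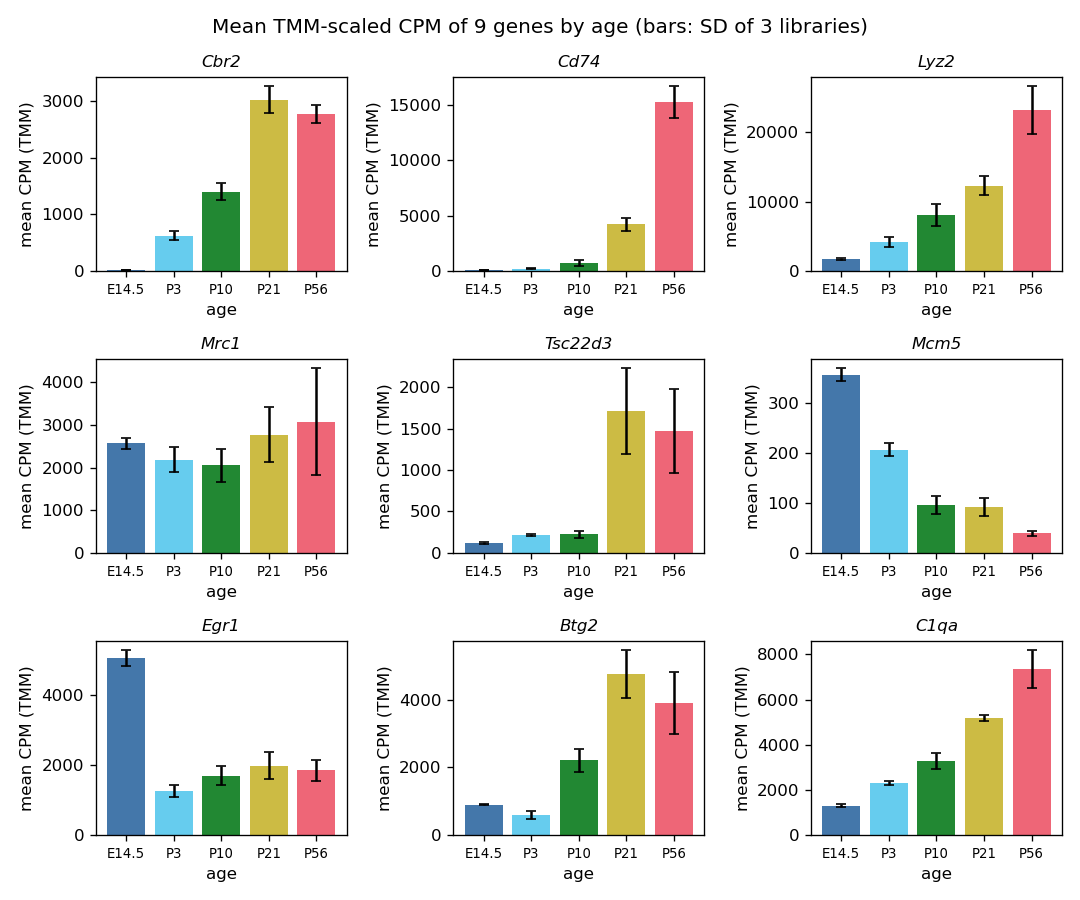
Mean TMM-scaled CPM of 9 genes at each age, with bars for the SD of 3 libraries. Cd74 rises from 53.5 to 15250 CPM and Mcm5 falls from 357 to 39.1 CPM between E14.5 and P56.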

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

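The alternatives with the fibroblast or mast cell marker sum as a covariate, and without 2 of the 3 E14.5 libraries, were chosen after the data were seen. Across the alternatives no result reversed. Of the gene counts 66 stayed within 1.5 times the value given, 14 rose above and 33 fell below it, and of the list counts 63, 1 and 7. Calls of single lists were the same in 2377 cases, gained in 64 and lost in 129, and those of named genes in 6900, 247 and 899. Both other scalings, and libraries thinned to the smallest total, kept each gene count within 1.5 times. DESeq2 called 822 (P3 vs E14.5), 336 (P10 vs P3), 760 (P21 vs P10), 528 (P56 vs P21) and 2761 genes (P21 vs E14.5) and 3190 in the F-test over 4 ages, and limma voom 99 (P10 vs P3) and 284 (P21 vs P10). Fits of the compared ages alone gave 681 (P3 vs E14.5), 73 (P21 vs P10) and 3 (P56 vs P21). No filter gave 116 (P10 vs P3) and 101 (P56 vs P21), and a filter of 5 CPM 91 (P10 vs P3). Requiring a log2 change of at least 1 left 186 (P3 vs E14.5), 37 (P10 vs P3), 111 (P21 vs P10) and 1186 (P21 vs E14.5), by construction. The replicate block gave 258 (P21 vs P10). The pairing of libraries by number was checked: of 18 pairs of equal number 0 had r above 0.1. Their mean r was 0.011 beside -0.005 for 36 other pairs, and 6 of 12 libraries correlated best with their own number. A strong pairing was not seen, and a weak one is not settled. The fibroblast covariate gave 31 (P3 vs E14.5), 0 (P56 vs P21, edgeR, with 802 at an unadjusted p under 0.05) and 382 (P21 vs E14.5). The mast cell covariate gave 34 (P3 vs E14.5), 6 (P21 vs P10) and 23 (P56 vs P21). Without 2 of the 3 E14.5 libraries, which differed from the other libraries in genes of the sex-linked list, 22 (P3 vs E14.5) and 374 (P21 vs E14.5) remained, of which 22 and 371 were among the genes called with all libraries; that fit has 1 library at E14.5, assumed to vary like the other ages. Leaving out 1 library at a time gave 127 to 198 genes (P3 vs E14.5), 21 to 41 (P10 vs P3), 30 to 171 (P21 vs P10), 37 to 100 (P56 vs P21), 1108 to 1933 (P21 vs E14.5), 1009 to 1851 (F-test) and 7 to 18 lists (P56 vs P21). An estimated correlation left 10 (P3 vs E14.5), 7 (P10 vs P3), 8 (P21 vs P10) and 3 lists (P56 vs P21), and fry 13 (P10 vs P3) and 7 (P56 vs P21). Apart from the log2 minimum, fewer libraries and the wider spread with covariates, the cause was not tested. On simulated data 3 libraries per age called at most 13.4% of genes changed 2-fold, so smaller changes were mostly not detectable.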

Other observations

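The tests of carried-over RNA (with both covariates), of the sources of MHC class II and of the glucocorticoid response genes were chosen after the results were seen; the splits of the libraries were planned.

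For each comparison of 2 ages, 10 splits of the 6 libraries exist, and 1 of them, the real one, reached the real count. They are too few for a share under 0.05. The real count and the highest other were 302 and 0 (P3 vs E14.5), 59 and 0 (P10 vs P3), 168 and 1 (P21 vs P10), 40 and 26 (P56 vs P21) and 1789 and 0 (P21 vs E14.5). The split with 26 genes put P56 replicate 4 with P21 replicates 1 and 2. For the F-test over 4 ages, 1 of 100 splits, the real one, reached 1759 genes, with 82 as the highest other. This argues against chance, though 100 splits cannot show a share smaller than 1 in 100.

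Fibroblast and mast cell genes varied between libraries of 1 age: as CPM of the total, summed fibroblast markers ranged from 82.8 to 789 CPM at E14.5 and from 818 to 3030 at P10, and mast cell markers from 638 to 1760 at P3 and from 10.2 to 292 at P56. RNA from fibroblasts (most abundant marker Col1a2, 703 ± 380 CPM at P10) and mast cells (Cpa3, 339 ± 177 CPM at P3), which the sort for CD206 should remove, is a candidate source: within ages the 14 fibroblast markers correlated at a mean r of 0.424 and the 9 mast cell markers at 0.519, at percentile 100 of 10000 random lists matched on expression (95th percentiles 0.076 and 0.14), and 0 of these genes are in another list. This does not tell RNA of another cell type from genes regulated together, since lists not tied to another cell type had high values too (0.47 for ribosomal protein, 0.487 for oxidative phosphorylation and 0.91 for mitochondrially encoded genes). Fibroblast RNA as the whole cause of the 40 changes from P21 to P56 was weighed with the marker sum as a covariate. A median share of 0.98 (quartiles 0.87 to 1.08) of the log2 change stayed, so as a set these genes followed the sum little within ages. The test cannot settle the cause, since genes that vary within ages are seldom called, and 0 of the 14 fibroblast markers were. All 40 genes kept their sign, but so did all called genes in each comparison, so the sign tells nothing. The calls ended (0 by edgeR, 802 at an unadjusted p under 0.05) because the median SE grew from 0.25 to 0.36, with Cd74 at 1.85 ± 0.25 before and 1.54 ± 0.33 after. The same limit holds for the 168 changes from P10 to P21 with the mast cell sum, where 0 of the 9 markers were called. There a median share of 1.02 (quartiles 0.89 to 1.16) stayed, the median SE grew from 0.23 to 0.32 and 6 genes were called (1344 at an unadjusted p under 0.05).

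The rise of MHC class II genes was weighed against other antigen-presenting cells, which the sort for CD206 should largely remove, and whose most abundant markers were Clec10a (775 ± 117 CPM at P21), also in the alternative activation list, and Ighm (789 ± 98.6 CPM), while Flt3 and Cd79a stayed below 1.1 CPM at each age. Over the span from E14.5 to P21, the median log2 change of the 11 tested dendritic cell markers was 1.15 (quartiles -0.08 to 2.63) beside 4.75 (2.09 to 7.27) for MHC class II genes. It was also lower at the steps to P3 (-0.32, -1.36 to 1.06, beside 1.89, 1.15 to 2.75) and to P56 (-0.02, -0.18 to 0.85, beside 1.74, 0.52 to 1.85). Such changes depend on how much of a marker the libraries already held at the younger age. The lower medians therefore cannot exclude dendritic cells as the whole cause. Dendritic cells also stay open at the steps to P10 (0.88, 0.4 to 2.26, beside 1.32, -0.61 to 2.05) and to P21 (1.29, -0.12 to 1.9, beside 1.94, 1.16 to 2.81), and their list itself passed over the span (4 of 11 up, 1 down, adjusted p = 0.0314 with an estimated correlation). B cell markers had a lower median than MHC class II genes at the step to P56 (-0.08, -1.48 to 0.36), with the same limit. B cells stay open there, at the steps to P3 (1.78, 0.17 to 2.86), P10 (0.18, -0.37 to 1.01) and P21 (0.48, 0.14 to 2.29) and over the span (2.30, 1.20 to 4.13). Without P21 replicate 1 the B cell marker median over the span on log2 CPM went from 1.367 to 0.352, and the list lost its call (adjusted p = 0.081). At the step to P3 the values conflict. Of the 6 tested B cell markers 2 were at the floor, with a list median of 1.46 at their bound. The sum over all 12 markers went down, from 585 ± 91.2 CPM of the total at E14.5 to 415 ± 94.4 at P3. For P56 vs P21 the median of 1.74 cannot be told apart from a difference between sequencing projects, because each project holds 1 of both ages; age itself stays open as untested.

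Glucocorticoid response genes rose from P10 to P21 with a median of 1.51. A scale factor as the cause is argued against, since it would move all genes alike: the lower quartile of the list was 1.07 beside a median of -0.01 for all genes, and camera, which compares the list with other genes, kept its call with an estimated correlation (adjusted p = 0.011). A single library is argued against, since the median on log2 CPM, 1.494 with all libraries, was at its lowest 1.27, without P21 replicate 3. Whether a handling response that also raised immediate early genes is part of it remains open. At the same step, from P10 to P21, the immediate early list was higher too, with a median of 0.84 and 7 of 21 members called by edgeR. From P3 to P10 the glucocorticoid list had a median of 0.16 (quartiles -0.2 to 1) beside 0.64 (0.44 to 1.11) for the immediate early list, which does not settle it. The labels give neither hormone level nor time of day, and both, like age, stay open as untested.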
